A study of Mus musculus with 4 samples.

How the data were processed

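RNA from mouse bone marrow mesenchymal stem cells was sequenced in 4 libraries, 2 from control mice carrying floxed Rheb alleles and 2 from mice that also carried Ucp1-Cre, which deletes Rheb in the brown adipocyte lineage. The strain was C57BL/6J, the age was 1 month, and all 4 animals were given as male in the labels. Per the labels' protocols, RNA was extracted with Trizol and mRNA libraries were made with a TruSeq v2 kit, which does not mark strand. Reads from a gene and from an antisense or overlapping partner therefore cannot be told apart. How the cells were isolated or cultured was not given in the sources used here.

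The deposited table holds whole-number read counts per gene, with gene coordinates, exon length and biotype, for 54532 Ensembl genes. Trimmomatic, HISAT2, featureCounts and the mm10 build were named, without versions, in the submitters' processing notes. The annotation release was not given in the sources used here. Of the 54532 gene IDs, 54495 were found in GENCODE M21, and 98.3% of those had the same chromosome, start and end, so coordinates are those of mm10 (GRCm38). How reads mapping to several places were counted was not given in the sources used here, so values of near-identical immunoglobulin segments, ribosomal protein genes and processed pseudogenes are uncertain one by one.

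Group and replicate number were taken from the sample titles. Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using genes kept by filterByExpr (14963 genes), TMM scaling and the quasi-likelihood F-test with group as the sole term, and Benjamini-Hochberg adjustment at 0.05. A standard error was taken as the absolute log2 fold change divided by the square root of F. Values per library are CPM (counts scaled to library size) after TMM scaling, and log2 ratios of single genes between libraries used CPM + 0.1. Medians of the fixed lists within a replicate number used log2 CPM with a prior count of 2. Those of B cell genes without immunoglobulin genes used CPM + 0.1, and ratios of the immunoglobulin sums used CPM alone. Total counts ran from 17425669 to 19001878, TMM factors from 0.997 to 1.003, and a count of 0 allows up to 3 counts, or 0.158 to 0.173 CPM. This limit covers counting error alone. With 2 libraries per group, an exact two-sided permutation test cannot go below p = 0.333, so the p-values rest on the spread that edgeR shares across genes.

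Before the data were examined, 37 gene lists were fixed: markers of stromal, blood and vascular lineages, and processes that fit the genotype. The 35 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 35 lists. A symbol on more than 1 row (105 symbols) was represented by its row with the most counts. The same was done with an estimated correlation and with fry. Named genes followed a rule fixed beforehand. It took Rheb and Ucp1 and, as no gene passed the threshold, the 6 genes with the smallest p in each direction (mean log2 CPM of at least 1, groups not overlapping, no predicted genes or pseudogenes). It also took up to 4 members of each described list by smallest p. Some genes that the rule takes are not reported here. Other genes named were chosen after their values were seen.

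The gene test was checked on 20 simulated data sets with the means and library sizes of these 14963 genes, 200 of them changed. It called 22.4% of genes changed 2-fold, 79.2% of those changed 4-fold and 91.6% of those changed 8-fold. A mean of 12.35 calls among 141.2 were false. The simulated libraries held no difference shared by replicate numbers, so these percentages need not hold for the real data. In 20 simulations, camera called 20 of 20 lists of 25 genes shifted by 0.5 on the log2 scale, and 1 of 600 lists left alone. Simulated genes were drawn independently of each other and lists were made of random genes. These numbers therefore give no false-call rate for lists whose members vary together.

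Alternatives fixed beforehand were median-of-ratios scaling, total counts alone, no low-count filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, other thresholds, camera with an estimated correlation and fry. Added after seeing the data were DESeq2 with a replicate block, the block without X and Y genes, the B cell list without immunoglobulin genes, and removal of a per-library trend with gene length and GC content. That trend used natural splines with 5 degrees of freedom each, with GC content taken from the longest GENCODE M21 transcript (a value for 99.9% of tested genes). Figures were drawn with matplotlib in Python.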

Results

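Gene expression was measured in bone marrow mesenchymal stem cells, the adherent stromal cells of marrow that can form bone, fat and cartilage, from 2 control mice and 2 littermates labelled as lacking Rheb in brown adipocytes. Rheb is the small GTPase that activates the kinase complex mTORC1. The comparison asks which genes of marrow stromal cells differ when Rheb is deleted in another tissue. Total counts were 18776563 and 19001878 in control replicates 1 and 2, and 17476868 and 17425669 in replicates 1 and 2 labelled knockout. Between 21520 and 22134 genes had at least 1 read per library. All 4 preparations also held reads of macrophage genes. Lyz2, a macrophage and neutrophil lysozyme chosen after its values were seen, had 6465 ± 1842 CPM in controls and 6440 ± 1064 CPM in the libraries labelled knockout (SD, n = 2 each).

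Replicate number went with sex-linked transcripts in both groups. Xist, the RNA of the inactive X chromosome, had 19502 counts in control replicate 1 and 31103 in the replicate 1 labelled knockout, against 8 and 2 in the corresponding replicates 2. The Y-linked gene Ddx3y had 1945 and 1631 counts in the replicates 2 and 0 in both replicates 1. The labels gave all 4 animals as male. Because each group held 1 library of each kind, values within replicate 1 and within replicate 2 are given beside the group values of Rheb, the immunoglobulin sum and the called lists. The first principal component held 45.8% of the variance and separated the replicate numbers, not the groups.

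**Figure D1:**
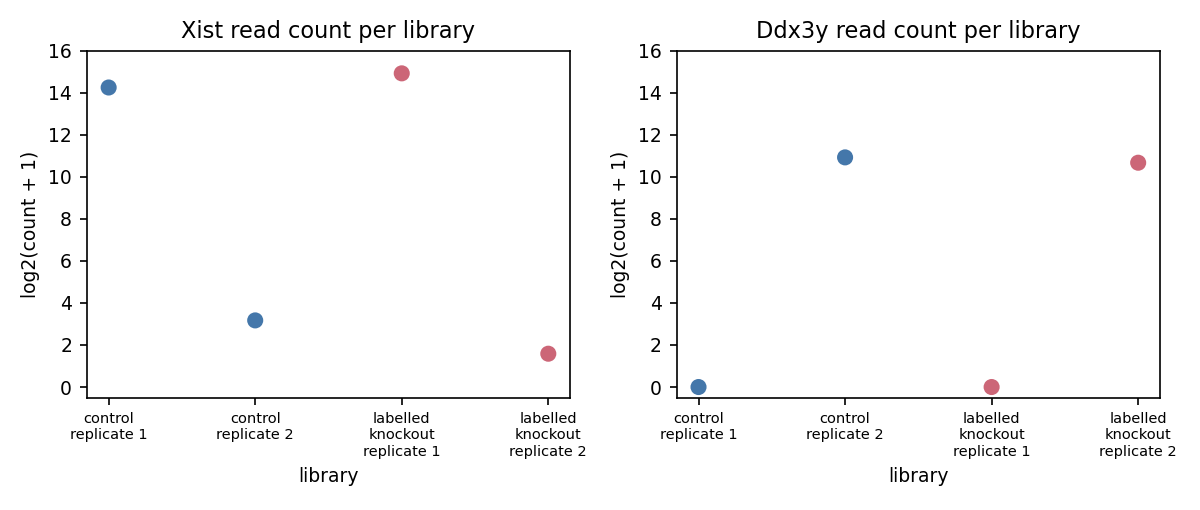
Read counts of Xist (left) and Ddx3y (right) in each library, as log2(count + 1), with controls in blue and libraries labelled knockout in red. Xist reached 19502 and 31103 counts in the replicates 1, and Ddx3y reached 1945 and 1631 counts in the replicates 2.

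Rheb (ENSMUSG00000028945; chromosome 5, 24802823 to 24842624, minus strand, protein coding) was higher in both libraries labelled knockout. Its level was 89.7 and 81.5 CPM in controls and 129.2 and 121.3 CPM in the libraries labelled knockout, a log2 fold change of 0.55 (SE 0.19), which did not pass edgeR's quasi-likelihood test over all genes (adjusted p = 1). Its unadjusted p was 0.0204 by edgeR and 0.00717 by edgeR with a replicate block, but the plan had fixed the adjusted p. The log2 ratio was 0.53 within replicate 1 and 0.57 within replicate 2. Ucp1-Cre acts in brown adipocytes, so Rheb in marrow cells shows the level in the profiled cells and does not check the deletion. Since the gene did not go down, the group is called labelled knockout throughout. Rheb does not exclude an exchange of the group labels, which would turn every direction given here. Ucp1 had 0, 0, 0 and 1 counts. The mTORC1 pathway list, with 13 of 28 tested members higher and 15 lower, was not called (adjusted p = 0.668). Its median was -0.04 and its mean 0.03, with the test directed upwards.

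No single gene passed the threshold. edgeR called 0 of 14963 genes (smallest adjusted p = 0.487), with 278 genes at an unadjusted p under 0.05 where chance gives 748. DESeq2 called 23 genes (4 higher, 19 lower), of which 12 were immunoglobulin genes, and had 234 at an unadjusted p under 0.05. limma-voom called 0, with 248. Without control replicate 1 edgeR called 183 genes, and without control replicate 2 it called 21. The groups did not overlap for 22.0% of genes, where chance gives 33.3%.

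The higher genes taken by the rule, which leaves out predicted genes and pseudogenes, were led by Cadm1, a cell adhesion molecule. Cadm1 had 20.6 and 14.2 CPM in controls and 51.9 and 65.7 CPM in the libraries labelled knockout. Its log2 fold change was 1.76 (SE 0.27, adjusted p = 0.636 by edgeR). The pseudogene Gm13410, left out by the rule, had a smaller unadjusted p by edgeR (4.63e-05 against 2.12e-04 for Cadm1). DESeq2 gave Cadm1 an adjusted p of 2.59e-05. Ret, the receptor tyrosine kinase for GDNF-family ligands, had 23.3 ± 1.24 CPM in controls and 51.6 ± 2.23 CPM in the libraries labelled knockout (SD, n = 2 each), a log2 fold change of 1.15 (SE 0.22, adjusted p = 0.767 by edgeR, 0.0229 by DESeq2 and 0.0569 by DESeq2 with a replicate block). The peptide transporter gene Slc15a2 had a log2 fold change of 1.78 (SE 0.38), the endothelial lipase gene Lipg 1.70 (SE 0.46), the kinase gene Hipk2 0.78 (SE 0.23) and Nhsl2 0.75 (SE 0.22). All 6 genes were higher within replicate 1 and within replicate 2, but the rule ensured this by taking only genes whose groups did not overlap.

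The 6 lower genes taken by the rule were B-lineage transcripts, 5 of them immunoglobulin segments. Jchain, the chain that joins IgA and IgM into polymers, had 44.7 and 24.9 CPM in controls and 7.25 and 3.17 CPM in the libraries labelled knockout (log2 fold change -2.74, SE 0.45, adjusted p = 0.699 by edgeR and 2.07e-07 by DESeq2). Igha had a log2 fold change of -3.11 (SE 0.57), Igkv15-103 -4.46 (SE 0.58), Ighv7-1 -4.51 (SE 0.68), Iglc1 -5.13 (SE 0.76) and Iglc2 -2.90 (SE 0.48). Igha had 17.9 and 64.6 CPM in controls, and its log2 fold change was -1.90 without control replicate 2. Reads of single segments can be shared with near-identical ones, so the family was also summed. All immunoglobulin genes together had 1114 and 621.4 CPM in controls and 224.9 and 113.6 CPM in the libraries labelled knockout, 5.13-fold lower by the means. The log2 ratio of the sums was -2.31 within replicate 1 and -2.45 within replicate 2. Of 52 tested immunoglobulin genes, 45 had lower values and 35 had an unadjusted p under 0.05. All 9 tested constant segments were lower, as were 36 of 43 variable segments.

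**Figure D2:**
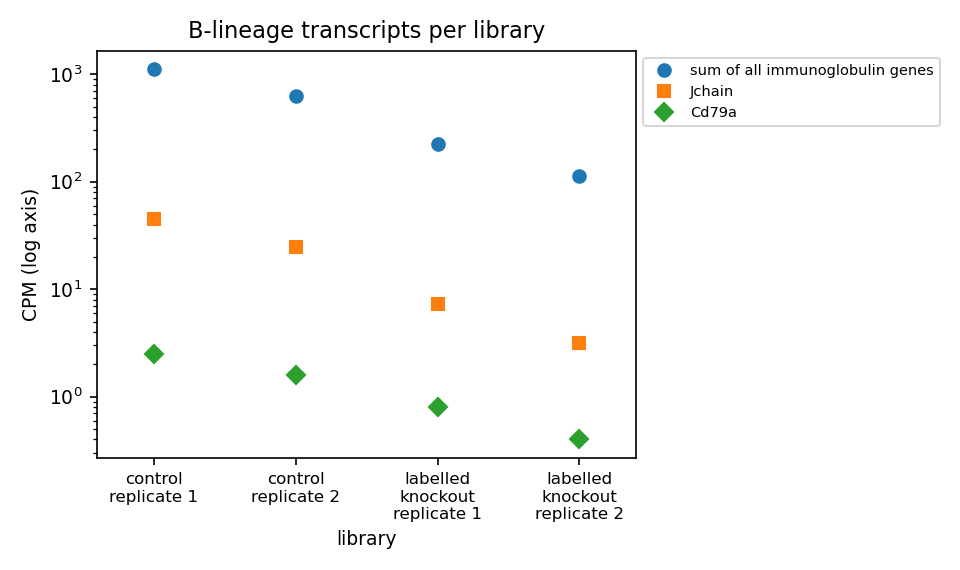
CPM on a log axis of the summed immunoglobulin genes, Jchain and Cd79a in each of the 4 libraries, 1 point per library. The immunoglobulin sum was 1114 and 621.4 CPM in controls and 224.9 and 113.6 CPM in the libraries labelled knockout. Not every B cell gene fell: Cd79b, not drawn, had 8.92 and 5.27 CPM in controls and 6.11 and 6.97 CPM in the libraries labelled knockout.

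Among the 35 gene lists tested, camera called 5 higher and 7 lower with its preset correlation, and 0 with an estimated correlation (lowest adjusted p = 0.769 with an estimated correlation). fry called 0 (lowest adjusted p = 0.564). With an estimated correlation, camera takes its degrees of freedom from the libraries, so with 4 libraries a list could hardly pass. Failing that test is no evidence that a list is unchanged. Estimated correlations reached 0.93 (dendritic cells) among called lists. They were -0.03 for the sterol list and -0.06 for skeletal muscle, under the preset 0.01, so correlation does not account for their loss. For replicate 2 against replicate 1 camera with its preset correlation called 10 lists. Median differences were also taken from mean log2 CPM. That between replicate numbers exceeded that between groups in size for the ribosomal protein (0.29 against -0.15), cell cycle (-0.34 against 0.23) and neutrophil lists (-0.77 against 0.42). Among the lists where it was smaller were the endothelial (0.27 against 0.28), megakaryocyte (0.69 against -0.81) and B cell lists (-1.05 against -1.57). For replicate 2 against replicate 1 camera called the B cell (adjusted p = 0.00132) and megakaryocyte lists (adjusted p = 0.0131) too. A crossed split set control replicate 2 and the replicate 1 labelled knockout against the other libraries. Its difference was larger in size for the osteoblast (0.59 against -0.41), fibroblast matrix (0.24 against -0.21), dendritic (-0.70 against 0.56) and neutrophil lists (-0.92 against 0.42). Over all genes, 0 members of any list passed by edgeR. By DESeq2 Iglc1 of the B cell list (adjusted p = 3.08e-08) and Ibsp (0.0229), Alpl (0.0298) and Sp7 (0.0329) of the osteoblast list passed, and of these 4, Iglc1 alone passed with a replicate block. With that block DESeq2 also called Igkc (adjusted p = 6.69e-20) and Ighm (adjusted p = 1.25e-18) of the B cell list. The 5 lists called higher were those for sterol and fatty acid synthesis, the cell cycle, endothelial cells, dendritic cells with MHC class II, and neutrophils. The 7 called lower were those for B cells, megakaryocytes and platelets, skeletal muscle, cytosolic ribosomal proteins, osteoblasts and bone matrix, fibroblast extracellular matrix, and Wnt targets and modulators. The direction was the same within replicate 1 and within replicate 2 for 7 of the 12.

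**Figure D3:**
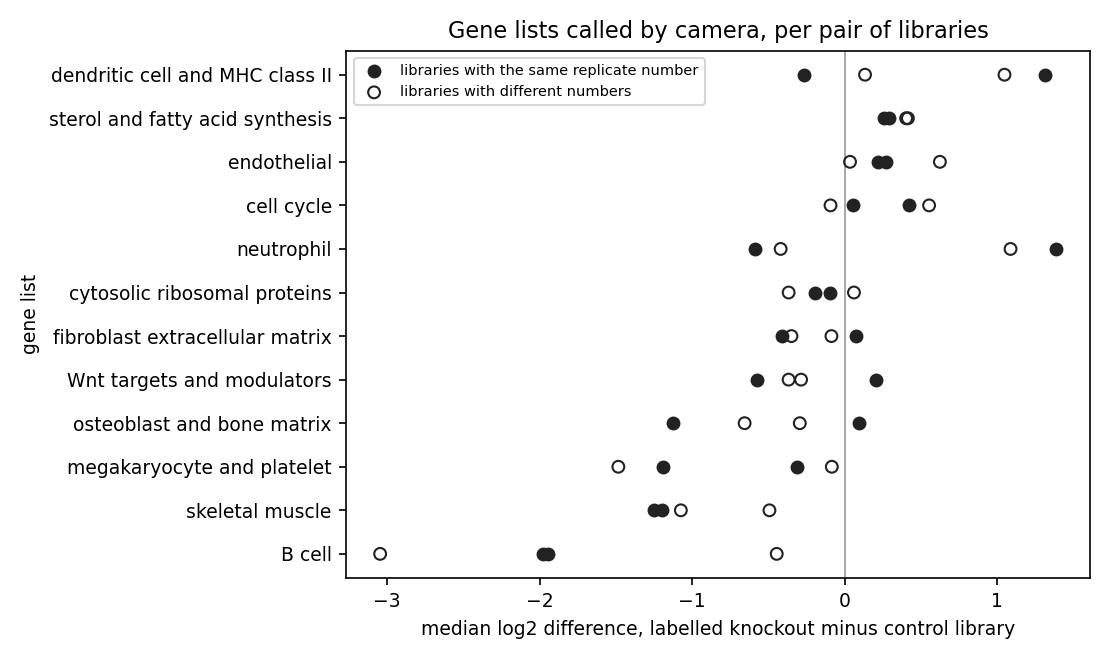
Median log2 difference of each called list between a library labelled knockout and a control library, with filled points for the same replicate number and open points for different numbers. The sterol and fatty acid synthesis list lay at 0.29 and 0.26 in the filled points, and the osteoblast and bone matrix list at 0.09 and -1.13.

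Genes of sterol and fatty acid synthesis were higher as a group, with 25 of 25 tested members at higher values and a median log2 fold change of 0.29 (camera adjusted p = 8.97e-08; adjusted p = 0.769 with an estimated correlation). Adjusted over the list alone, 0 members passed. The fatty acid desaturase gene Scd1 had a log2 fold change of 0.60 (SE 0.22), the lanosterol synthase gene Lss 0.49 (SE 0.21) and the fatty acid synthase gene Fasn 0.45 (SE 0.20). The list median was 0.29 within replicate 1 and 0.26 within replicate 2. Cell cycle genes had 33 of 34 members at higher values (median 0.21, camera adjusted p = 2.82e-05; adjusted p = 0.871 with an estimated correlation), with 0 passing adjusted over the list alone. Mki67, a marker of dividing cells, had a log2 fold change of 0.52 (SE 0.30). The cell cycle median was 0.05 within replicate 1 and 0.42 within replicate 2. Without control replicate 2 the list was no longer called (median 0.01, adjusted p = 0.867), and the median was 0.51 without control replicate 1 and 0.13 without the replicate 1 labelled knockout.

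The B cell list was lower, with 9 of 10 members at lower values and a median log2 fold change of -1.85 (camera adjusted p = 1.57e-07; adjusted p = 0.871 with an estimated correlation). Adjusted over the list alone, 5 members passed, among them Igkc, Ighm, Iglc1 and Cd79a. Igkc had a log2 fold change of -2.48 (SE 0.55) and Ighm -2.60 (SE 0.59). The list median was -1.95 within replicate 1 and -1.98 within replicate 2, -1.12 without control replicate 1 and -2.87 without the replicate 1 labelled knockout. With the filter of 5 CPM, which kept 5 members (Cd79b, Ighm, Igkc, Ebf1 and Blnk), the median was -0.11 and the list was still called (adjusted p = 0.00166). Without its immunoglobulin genes, 6 of 7 members had lower values (median -1.38, camera adjusted p = 0.00413; adjusted p = 0.871 with an estimated correlation), with medians of -0.81 and -0.51 within replicates 1 and 2. These within-replicate medians used CPM + 0.1, unlike those of the whole list. The megakaryocyte and platelet list had 9 of 10 members at lower values (median -0.71, camera adjusted p = 3.81e-05; adjusted p = 0.871 with an estimated correlation), with 0 passing adjusted over the list alone. Ppbp, a platelet chemokine gene, had a log2 fold change of -0.65 (SE 0.30) and Itga2b, a platelet integrin gene, -0.81 (SE 0.44). The megakaryocyte median was -1.19 within replicate 1 and -0.31 within replicate 2. Without the replicate 1 labelled knockout that list had a median of -0.23 and was not called (adjusted p = 0.431), and the median was -0.43 without control replicate 2 and -1.36 without the replicate 2 labelled knockout.

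The skeletal muscle list had 5 of 5 members at lower values (median -1.31, camera adjusted p = 5.70e-05; adjusted p = 0.788 with an estimated correlation), and 1, Mylpf, passed adjusted over the list alone. Mylpf had 2.40 and 1.79 CPM in controls and 0.343 and 0.691 CPM in the libraries labelled knockout. The list median was -1.25 within replicate 1 and -1.20 within replicate 2. Only 5 of the 14 listed genes had enough reads to be tested. Tnni2 had a log2 fold change of -0.05, with 0.88 within replicate 1 and -0.62 within replicate 2. With the filter of 5 CPM too few members remained to test the list. Cytosolic ribosomal protein genes had 46 of 51 members at lower values, by a small amount (median -0.15, camera adjusted p = 7.75e-04; adjusted p = 0.871 with an estimated correlation; 0 passing adjusted over the list alone). Rpl19 had a log2 fold change of -0.24 (SE 0.22), and the list median was -0.20 and -0.09 within replicates 1 and 2. That list was not called without control replicate 2 (median -0.07, adjusted p = 0.354) or without the replicate 1 labelled knockout (median -0.04, adjusted p = 0.903). Its median was -0.27 without the replicate 2 labelled knockout and -0.09 with length and GC trends removed. The endothelial list had 13 of 14 members at higher values (median 0.25, camera adjusted p = 5.04e-04; adjusted p = 0.871 with an estimated correlation; 0 passing adjusted over the list alone). Ptprb, an endothelial phosphatase gene, had a log2 fold change of 0.65 (SE 0.22) and Stab2, a sinusoidal scavenger receptor gene, 0.79 (SE 0.29). The endothelial median was 0.22 and 0.27 within replicates 1 and 2. It was not called without control replicate 1 (median 0.16, adjusted p = 0.110) or without the replicate 2 labelled knockout (median 0.09, adjusted p = 0.274), and it was 0.51 without control replicate 2 and 0.41 without the replicate 1 labelled knockout.

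Osteoblast and bone matrix genes were lower over all 4 libraries, with 13 of 15 members at lower values and a median log2 fold change of -0.65 (camera adjusted p = 0.00150; adjusted p = 0.871 with an estimated correlation). Adjusted over the list alone, 3 members passed: Alpl, the alkaline phosphatase of mineralising cells, Ibsp, a bone matrix sialoprotein, and Sp7, an osteoblast transcription factor. Alpl had 34.7 and 122 CPM in controls and 24.6 and 20.5 CPM in the libraries labelled knockout (log2 fold change -1.80, SE 0.51), Ibsp a log2 fold change of -2.13 (SE 0.61), Sp7 -2.15 (SE 0.61) and Smpd3 0.91 (SE 0.35). The list median was 0.09 within replicate 1 and -1.13 within replicate 2. Alpl, Ibsp and Sp7 had log2 ratios of -0.50, -0.74 and -0.51 within replicate 1, and -2.57, -2.77 and -3.15 within replicate 2. Smpd3 was higher in both (0.62 and 1.33). Without control replicate 2 the median was 0.01 and the list was not called (adjusted p = 0.378), and without the replicate 2 labelled knockout it was -0.30 (adjusted p = 0.200). The median was -1.19 without control replicate 1 and -0.29 with the filter of 5 CPM, and with no low-count filter the list was not called (adjusted p = 0.0512). The fibroblast extracellular matrix list (26 of 35 members lower, median -0.19, camera adjusted p = 0.0161; adjusted p = 0.871 with an estimated correlation) had medians of 0.07 and -0.41 within replicates 1 and 2. The list of Wnt targets and modulators (15 of 20 members lower, median -0.33, camera adjusted p = 0.0230; adjusted p = 0.871 with an estimated correlation) had medians of 0.20 and -0.58. In both, 0 members passed adjusted over the list alone. With replicate number as a term neither was called (adjusted p = 0.0709 and 0.130), and without control replicate 2 neither was called (medians 0.10 and 0.07, adjusted p = 0.944 and 0.603). Without the replicate 2 labelled knockout neither was called (medians -0.16 and -0.17, adjusted p = 0.482 for both), nor with no low-count filter (adjusted p = 0.0574 and 0.0699). The Wnt list was also lost with the filter of 5 CPM (adjusted p = 0.116). Without the replicate 1 labelled knockout the medians were -0.34 and -0.57.

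**Figure D4:**
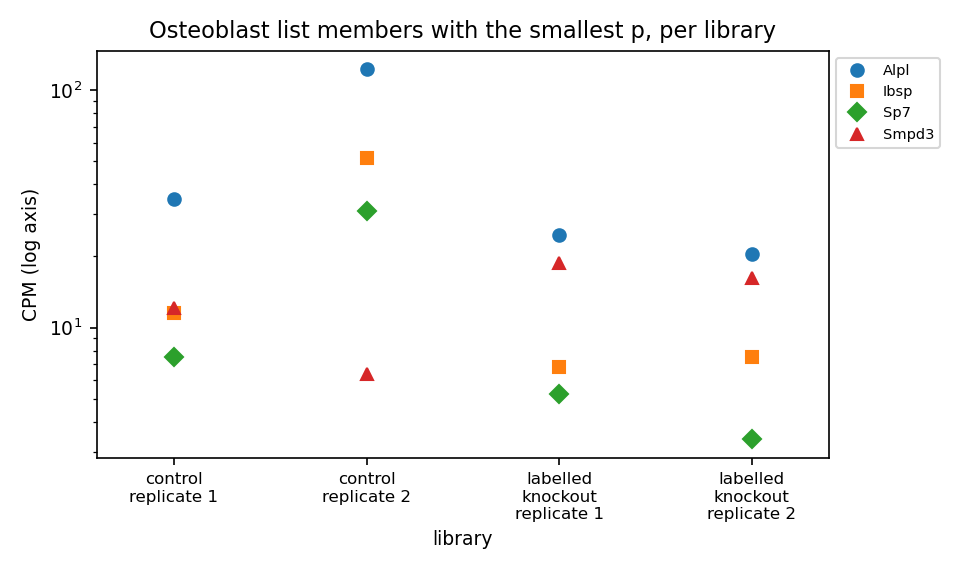
CPM on a log axis of the 4 osteoblast list members with the smallest p, 1 point per gene and library. Alpl, Ibsp and Sp7 had their highest values in control replicate 2 (122, 51.5 and 30.9 CPM), and Smpd3 its lowest value there (6.37 CPM).

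Markers of other blood cells differed in direction between the replicate numbers. The dendritic cell and MHC class II list had 9 of 9 members at higher values (median 0.67, camera adjusted p = 5.49e-04; adjusted p = 0.871 with an estimated correlation), but medians of -0.27 and 1.31 within replicates 1 and 2. Itgax, an integrin gene of dendritic cells, had 92.9 and 43.2 CPM in controls and 86.5 and 202.7 CPM in the libraries labelled knockout. The list was not called without the replicate 2 labelled knockout (median -0.04, adjusted p = 0.961) or without control replicate 2 (median 0.51, adjusted p = 0.0883), nor with no low-count filter (adjusted p = 0.390), and its median was 1.09 without the replicate 1 labelled knockout. The neutrophil list had 14 of 18 members at higher values (median 0.18, camera adjusted p = 0.00664; adjusted p = 0.871 with an estimated correlation), with medians of -0.59 and 1.38 within replicates 1 and 2. Without control replicate 2 it was called in the opposite direction (median -0.50, adjusted p = 3.12e-05), and without the replicate 2 labelled knockout it was not called (median 0.09, adjusted p = 0.274), nor with no low-count filter (adjusted p = 0.0877). The neutrophil median was 1.25 without control replicate 1 and 0.38 with a replicate block. In neither list did a member pass adjusted over the list alone. The macrophage and monocyte list was not called (median 0.07, adjusted p = 0.224; -0.40 and 0.62 within replicates 1 and 2), nor were the T and NK cell list (adjusted p = 0.863) or the osteoclast list (adjusted p = 0.185; -0.18 and 0.46).

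The lists for stromal niche factors, mesenchymal surface markers, white adipocytes and chondrocytes were not called. The stromal niche list, which holds Cxcl12, had a median of -0.30 (adjusted p = 0.133; 0.27 and -0.74 within replicates 1 and 2), mesenchymal surface markers a median of 0.16 (adjusted p = 0.645), white adipocyte genes 0.08 (adjusted p = 0.107) and chondrocyte genes -0.11 (adjusted p = 0.651; 0.12 and -0.61). Cxcl12 had 431 and 892.1 CPM in controls and 506.4 and 359 CPM in the libraries labelled knockout. Brown adipocyte and erythroid lists had 4 tested members each and were not tested. BMP and TGF-beta signalling (adjusted p = 0.695), nuclear oxidative phosphorylation (adjusted p = 0.107), glycolysis and hypoxia (adjusted p = 0.107), interferon response (adjusted p = 0.870) and the unfolded protein response (adjusted p = 0.870) were not called either. The remaining 10 lists were not called (smallest adjusted p = 0.133). Besides mTORC1, the signs of median, mean and test differed for the T and NK cell, mast cell and basophil, osteoclast regulator, erythropoietin signalling and unfolded protein response lists.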

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

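Replicate numbers were shared between groups, and the labels do not say that they pair the animals. Deviations of same-numbered libraries correlated across genes at 0.246 (0.176 without X and Y genes). With a replicate block edgeR again called 0 genes, and camera called 10 lists. The smallest adjusted p of that edgeR fit was 0.101, for Ighv7-1 and Igkv15-103, and Jchain had 0.147. DESeq2 called 23 genes, and 14 with a replicate block, a choice made after seeing the data; 10 of the 14 were among the 23. Leaving out 1 library at a time gave 0 to 183 genes, 7 to 21 lists and a Rheb log2 fold change of 0.49 to 0.62, never past the threshold. A lone library was then assumed to vary like the other group. Lists called numbered 7 with no low-count filter, where more genes were tested, and 0 both with an estimated correlation and by fry. Without control replicate 2 the test of 3 called lists changed direction: over the libraries left out, medians ran from -0.34 to 0.10 for fibroblast extracellular matrix, -0.50 to 1.25 for neutrophils and 0.0138 to 0.51 for the cell cycle. The cause was not tested. Sterol, B cell and skeletal muscle lists stayed called in their direction with each library left out. The skeletal muscle list could not be tested with the filter of 5 CPM. Rheb was never called in its 14 alternatives, and 0 genes were called in the 12 alternatives for gene counts other than DESeq2 and the 2 without a control library. Removing length and GC trends, also chosen after seeing the data, left all 12 lists called. Alternatives for FPKM values were not run, as the table holds counts. With 2 libraries per group, the simulated data gave calls for 22.4% of genes changed 2-fold. At 4-fold and 8-fold the percentages were 79.2% and 91.6%, from libraries without a difference between replicate numbers.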

Other observations

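All of the tests of explanations below were chosen after the result was seen. A list of myogenic genes outside the fixed skeletal muscle list was written after Myl1 and others of its members were seen, and was not tested as a set. Of 13 tested members, 11 had lower values and 8 an unadjusted p under 0.05 by edgeR. Over all genes 0 passed by edgeR, and Myl1 passed by DESeq2 (adjusted p = 0.0458) but not by DESeq2 with a replicate block. Mef2c (log2 fold change 0.04) and Cdh15 (0.13) were not lower. Myl1, a myosin light chain gene, had 34 and 18 counts in controls and 0 in both libraries labelled knockout, and Actc1, cardiac actin, 31 and 18 against 0 and 0. Myog, a transcription factor of myoblast fusion, had 16 and 14 counts against 1 and 1, and Myh3, embryonic myosin, 52 and 31 against 4 and 0. All of these counts were close to the low-count limit of the test.

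A few transcripts were present in one group alone. With at least 10 counts in both libraries of one group and 0 in both of the other, 6 genes split by group, 4 by replicate number, all 4 on the Y chromosome, and 2 by the crossed split. The 6 were Myl1, Actc1, Igkv3-5 and Igkv3-2 in controls and the processed pseudogenes Gm13410 (65 and 52 counts) and Gm29718 (16 and 17 counts) in the libraries labelled knockout. Gm9008 had 0 and 2 counts in controls and 30 and 88 in the libraries labelled knockout, and the pseudogene Tma7-ps 39 and 57 against 2 and 5. The adjusted p by DESeq2 was 2.84e-04 for Gm13410, 0.00305 for Gm9008 and 0.0359 for Tma7-ps. With a replicate block DESeq2 called Gm9008 (adjusted p = 0.00744) but not Gm13410 or Tma7-ps. Gm13410 lies on chromosome 2 at 24178834 to 24180317 and Gm9008 on chromosome 6 at 76495432 to 76497784 (mm10).

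Immunoglobulin transcripts were lower in the libraries labelled knockout. A smaller share of all blood cells, large enough for this drop, is argued against by the macrophage and monocyte list. Its median log2 fold change was 0.0688, with -0.40 within replicate 1 and 0.62 within replicate 2. Other blood lists were mixed, with medians of -0.71 for megakaryocytes and 0.18 for neutrophils. Splitting of reads between near-identical segments is argued against by the summed CPM (log2 ratio -2.36). The difference between replicate numbers is argued against too, since the smaller of the within-number ratios was -2.31. Whether there were fewer B and plasma cells, or less of their RNA, stays open: other B and plasma cell genes, without the 4 that prompted the list, had a median of -1.38, with 5 of 7 lower, but -0.81 within replicate 1 and 0.40 within replicate 2. Of these, Bank1 (log2 fold change 0.55) and Cd22 (0.52) were higher, and Cd79b was lower by a small amount (-0.12). Also open are a chance difference between 4 animals and an untested effect of genotype.

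Replicates 1 and 2 differed in both groups. Cells from female animals in both replicates 1 may account for the sex-linked reads, as the lower Xist count there was 19502 and Y-linked counts were at most 1, which goes against the label. For replicate 2 against replicate 1 edgeR called Xist, Kdm5d and Ddx3y. In a fit of autosomal genes it called 0 (smallest adjusted p = 0.301). Sex-chromosome genes alone are argued against only by the unadjusted p-values, with 2240 autosomal genes under 0.05 where chance gives 724. A trend with length and GC content may account for most of these: log2 differences correlated with GC content across genes (Spearman 0.629, genes not being independent), and a fit with the trend removed gave 785 such genes, where chance gives 723. Whether that trend came from library preparation or the animals was not tested.

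The lower osteoblast list may rest on control replicate 2: without it the median log2 fold change was 0.0093. A smaller share of stromal cells stays open, as stromal lists moved apart. Mesenchymal surface markers had a median of 0.16 (SE 0.11), fibroblast extracellular matrix -0.19 (SE 0.08) and stromal niche factors -0.30 (SE 0.13). The osteoblast list had -0.65 (SE 0.28). These SEs of a median come from the spread of member genes taken as independent. They hold no spread between animals and do not test whether the lists differ. Within replicate 2 the niche median was -0.74, that of the matrix list -0.41 and that of the surface markers 0.22. For the osteoblast list median, an effect of genotype seen only in the replicates 2 stays open and was not tested. Alpl, Ibsp and Sp7 were also lower within replicate 1, by a smaller amount.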
